A study of Mus musculus with 9 samples.

How the data were processed

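RNA sequencing was carried out on LT-HSCs sorted from the bone marrow of C57BL/6 mice, in 3 groups of 3 libraries: young, aged, and aged with the RhoA inhibitor Rhosin at 100 µM. Per the labels' protocols, cells were kept for 16 h in a balanced salt solution with 10% serum at 3% oxygen and 5% carbon dioxide, and libraries were made with SMART-Seq v4 and Nextera XT. The labels give the sequencing batch of each library: young 2, aged 2, aged+Ri 2 and aged+Ri 3 in batch 2, aged 1 and aged+Ri 1 in batch 1, young 3 and aged 3 in batch 3, and young 1 in batches 1 and 3. The labels call the libraries biological replicates and do not say how many mice each holds, so p-values reflect the spread between these samples.

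The table of 21939 genes by 9 libraries holds estimated counts as deposited by the authors, since between 71.6% and 80.9% of the values in a library are whole numbers within 0.005 and the rest are not. Per the submitters' processing notes, reads were processed with cutadapt 1.18, STAR 2.7.0, SAMtools 1.14, R 4.2.0 and featureCounts (version not given in the sources used here) for the build GRCm38. The estimated counts were rounded to whole numbers here before any count model. Gene coordinates come from the GRCm38 annotation, in which 21447 symbols were matched. The counting is not stated to use strand, so genes that overlap another gene are uncertain. No pair of libraries agreed within sampling noise.

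Library totals were between 34358101 and 72503142 counts. Genes were kept by edgeR's filterByExpr with the groups, which left 15127, and 240 genes had 0 in every library. Counts were scaled by TMM, and 1 quasi-likelihood model of group means was fitted to all 9 libraries (edgeR 4.0.16, glmQLFit with robust estimation and its default method, in R 4.3.3), which leaves 6 residual degrees of freedom. Each comparison was tested with edgeR's two-sided quasi-likelihood F-test, Benjamini-Hochberg adjustment over the genes tested, and a threshold of 0.05. Fold changes are log2 with standard errors, and CPM values are TMM-normalised means ± SD. A fitted change of a gene with 0 to 3 counts in a group depends on the prior count. For such genes the ratio of group totals is given with its exact Poisson 95% interval, or as a lower bound at 3 counts over the group. Intervals and floors cover counting error only.

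Before the data were examined, 32 gene lists with 1407 members were fixed, of which 1396 members were in the table, together with the model, the alternatives and the rule for naming genes. The lists cover HSC ageing, HSC identity and quiescence, RhoA and actomyosin, SRF and MRTF targets, YAP and TAZ targets, nuclear envelope and lamina, heterochromatin, adhesion, homing and polarity, and nucleic acid sensing. Further lists cover interferon response, NF-kB and inflammation, unfolded protein and integrated stress response, heat shock, immediate early genes, NRF2, p53 and senescence, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, cholesterol synthesis, S phase, and G2 and M phase. Markers of cell types cover megakaryocyte, myeloid, lymphoid, erythroid, mature T, NK and B cells, macrophage and dendritic cells, mast cells and basophils, stromal and endothelial cells, and sex-linked genes. The 31 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 93 tests. With an estimated correlation 0 lists passed in any comparison, and with fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, 1, 3 and 6 did in the order of the comparisons (camera passed 4, 14 and 12).

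Genes named in the text were those past the threshold with groups that do not overlap and at least 5 CPM in the higher group, predicted genes left out. Up to 10 per direction were taken by size of change, or 5 for aged+Ri against young. Places left over went to the genes with the smallest unadjusted p under the same conditions. Up to 4 members of a list with the smallest p could be named, as could Rhoa, Rhob, Rhoc, Cdc42, Klf4, Lmna, Selp, Vwf and the sex-linked genes.

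The alternatives were DESeq2 size factors, DESeq2 1.42.0, limma-voom with sample weights, no filter, a filter of at least 10 counts in every library of a group with a mean of 5 CPM, only the 2 groups compared, the replicate number as a block, the sequencing batch as a covariate, and each library left out in turn. Added after the data were seen were young 1 as the only young library and edgeR's newer quasi-likelihood method. Single measures were compared by two-sided exact permutation tests over 20 assignments, with a smallest p of 0.1 for 3 against 3 libraries. Predicted satellite-like genes are a set of 12 chosen after their counts were seen.

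The steps were tested on simulated data with 200 changed genes, drawn with the dispersions that edgeR fitted to these libraries. For aged against young, edgeR recovered 30% of genes changed 4-fold and 78% of those changed 16-fold, with 3 false calls among 111. For aged+Ri against aged it recovered 26% and 68%, with 7 false among 101, and for aged+Ri against young 25% and 67%, with 1 false among 93. DESeq2 recovered 47% and 90%, 47% and 90%, and 43% and 92% in these comparisons, with 121 false among 258 calls, 139 among 276 and 148 among 283. limma-voom recovered 19% and 60%, 16% and 49%, and 21% and 61%, with 4, 0 and 0 false calls. In 20 simulations of aged+Ri against aged without change, camera called 1 of 620 lists. Genes were drawn independently there, while in the data the estimated correlation reached 0.68 for ribosomal protein genes in aged against young. This rate therefore does not cover lists whose genes move together.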

Results

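Gene expression was measured by RNA sequencing in long-term haematopoietic stem cells (LT-HSCs) sorted from mouse bone marrow as lineage-negative, Sca1+, cKit+, CD34- and Flt3- cells. The 9 libraries form 3 groups of 3 biological replicates: cells of young mice (10 to 16 weeks), cells of aged mice (over 80 weeks), and cells of aged mice kept with Rhosin, an inhibitor of the small GTPase RhoA, at 100 µM (aged+Ri). All cells were held in culture for 16 h before lysis. Total counts per library were 53726683, 35974758 and 34358101 in the young group, 72503142, 57374461 and 57045939 in the aged group, and 37712059, 55708258 and 38447858 in the aged+Ri group. At these totals, 3 counts in a library correspond to between 0.0414 and 0.0873 CPM, counts scaled to the size of the library.

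The young libraries differed from the rest in ways that accompany every comparison with them. A count was found for 20600 ± 557 genes in young (mean ± SD, n = 3), 16220 ± 1560 in aged and 15660 ± 618 in aged+Ri libraries. Among predicted genes with satellite-like counts, the share of all counts was 2.90% ± 1.81 in young and 0.141% ± 0.15 in aged libraries (n = 3 each). Transcripts of the Y chromosome were abundant in young 2 and young 3 only, where Ddx3y had 2577 and 6400 counts, against at most 1 count in each of the other 7 libraries. Another Y gene, Kdm5d, had 869 and 968 counts in these libraries, 58 in aged+Ri 1 and at most 2 in the rest. Iglc2, an immunoglobulin light-chain gene of B cells, took 1.23% of the counts of young 1. For these group differences, two-sided exact permutation tests gave p = 0.1 for genes detected and for satellite-like counts (adjusted p = 0.162 for both, Benjamini-Hochberg), the smallest value 3 against 3 libraries allow. The satellite-like genes were chosen after their counts were seen, so the p for them is no separate evidence. The first principal component of log2 CPM held 30.5% of the variance and placed the 3 young libraries between -189.6 and -98.1 and the other 6 between 1.99 and 109.7.

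**Figure D1:**
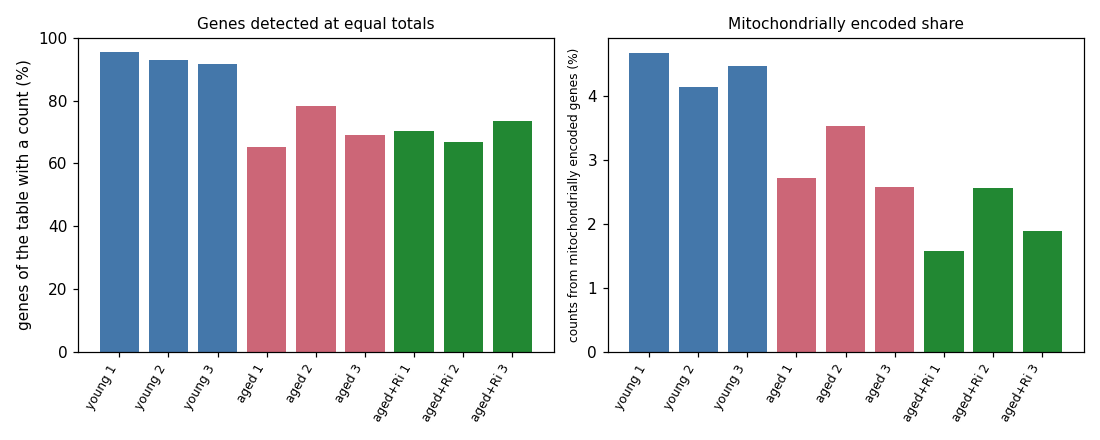
Percent of the 21939 genes with at least 1 count after every library was thinned to 34358101 counts (left) and percent of counts from mitochondrially encoded genes (right), 1 bar per library. The young libraries lie between 91.7% and 95.4% of genes detected, and the other 6 between 65.1% and 78.3%.

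The comparison of aged with young LT-HSCs asks which transcripts differ with the age of the mouse. Genes that many studies find higher in aged HSCs rose as a group in the camera test (adjusted p = 0.169 with an estimated correlation, so that call was lost there), and 5 single genes rose past the threshold. Sbspon, which encodes a secreted thrombospondin-domain protein, was at 72.5 ± 15.6 normalised CPM in aged and 0.141 ± 0.0517 in young cells (n = 3 each), a log2 change of 8.99 ± 0.71 (SE; edgeR adjusted p = 0.000132). Ramp2, a partner of the calcitonin receptor-like receptor, rose by 8.23 ± 1.09 on the log2 scale, from 0.2096 ± 0.184 to 64.2 ± 36.5 CPM (edgeR adjusted p = 0.0137). Gpx8, a peroxidase of the endoplasmic reticulum, rose by 8.18 ± 1.15 to 25.6 ± 9.93 CPM (edgeR adjusted p = 0.0207). Spryd4, a SPRY-domain gene, rose by 7.65 ± 1.00 to 11.98 ± 2.07 CPM (edgeR adjusted p = 0.0137). Snrpn, an imprinted gene for a spliceosomal protein, had 3 counts in the young and 2982 in the aged group, a ratio of 642 (95% counting interval 219.6 to 3117; edgeR adjusted p = 0.00772).

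In GRCm38, Sbspon lies on chromosome 1 at 15853862 to 15892722 and Ramp2 on chromosome 11 at 101246028 to 101259546. Gpx8 lies on chromosome 13 at 113042753 to 113046410, Spryd4 on chromosome 10 at 128209908 to 128211807 and Snrpn on chromosome 7 at 59982495 to 60140219. Snrpn shares its locus with Snurf, which is listed at 0 in all 9 libraries, so counts of the pair are uncertain. Each of the 5 genes was higher in 3 of 3 aged libraries than in every young one, which the naming rule required.

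The list of genes reported higher in aged HSCs rose as a group: 57 of 64 measured members had a positive log2 change, with a median of 1.03. Sbspon and Ramp2 passed over all genes, and 17 members were higher and 0 lower at an edgeR p adjusted over the list alone. Plscr2, a phospholipid scramblase gene, was at 611 ± 198 CPM in aged and 210.2 ± 42.1 in young cells (edgeR adjusted p = 0.129). Nupr1, a stress-induced nuclear regulator, was at 2177 ± 610 and 749.5 ± 290 (edgeR adjusted p = 0.129). The group test gave a camera adjusted p = 2.2e-16, with a range over its alternatives from 5.22e-20 to the highest, an adjusted p = 0.169 with an estimated correlation. Within batch 2 the median was 1.45 and within batch 3 it was 1.88.

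Interferon-response genes rose as a group with a small median of 0.14 over 69 measured members, 37 of them positive (camera adjusted p = 0.0192). The call had an adjusted p = 0.333 with an estimated correlation, the highest of its alternatives, of which the lowest was 2.35e-05. Ifit1, an antiviral RNA-binding protein, was at 16.1 ± 17.4 CPM in aged and 0.1761 ± 0.149 in young cells, and Ifi27 at 101.7 ± 40.1 and 32.7 ± 9.09, with edgeR adjusted p of 0.0986 and 0.196. Genes of the unfolded protein and integrated stress response also rose as a group, with a median of 0.26 and 32 of 56 members positive (camera adjusted p = 0.0203; adjusted p = 0.834 with an estimated correlation, where the lowest of its alternatives was 2.91e-05). Asns, asparagine synthetase, was at 146 ± 5.48 CPM in aged and 35.1 ± 19.9 in young cells (edgeR adjusted p = 0.173). The median over all genes was -0.126, and camera compares a list with the other genes, so lower other genes may add to both calls. With fry the adjusted p was 0.173 for interferon response and 0.606 for the unfolded protein and integrated stress response. The interferon response median was 0.05 without aged 3, and 0.23, 0.25 and 0.33 without young 2, aged 1 and aged 2. Without young 1 the unfolded protein and integrated stress response call was lost, with a median of 0.19 and a camera adjusted p = 0.125. With the stricter filter both calls were lost, interferon response at a camera adjusted p = 0.0986 and the unfolded protein and integrated stress response at 0.299. In batch 2 and in batch 3 the medians were 0.17 and 0.56 for interferon genes, and 0.02 and 0.19 for unfolded protein genes.

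All 13 mitochondrially encoded genes were lower in aged cells, and the list fell as a group with a median of -0.64 (camera adjusted p = 0.00169; adjusted p = 0.662 with an estimated correlation, where the lowest of its alternatives was 3.77e-06). mt-Nd2, a subunit of respiratory complex I, was at 502 ± 139 CPM in aged and 1228 ± 70.3 in young cells (edgeR adjusted p = 0.176). The share of counts from these 13 genes, a common measure of RNA and cell quality, was 2.94% ± 0.522 in aged and 4.43% ± 0.273 in young libraries. Within batch 2 the median of the mitochondrially encoded list was -0.05 and within batch 3 it was -0.95. Its call was lost without aged 1 (median -0.50, camera adjusted p = 0.0855) and without a filter on low counts (-0.50, 0.164).

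Next in the fixed order of naming were genes that did not pass. Fcor, a repressor of Foxo1, had 2 counts in the young and 3385 in the aged group, a ratio of 1094 (counting interval 302.6 to 9035; edgeR adjusted p = 0.0539). Eya4, a transcriptional coactivator with phosphatase activity, was at 23.8 ± 2.43 CPM in aged and 0.4306 ± 0.143 in young cells (edgeR adjusted p = 0.0584). Nrgn, a calmodulin-binding protein, was at 576 ± 156 and 120.6 ± 28.3 (edgeR adjusted p = 0.0626). Eif2b3, a subunit of the translation factor eIF2B, and Trdmt1, a tRNA methyltransferase, had log2 changes of 4.21 and 6.33 (edgeR adjusted p = 0.0986 for both). On the lower side, the deadenylase subunit gene Pan3 was at 60.5 ± 4.74 CPM in aged and 179 ± 8.88 in young cells (log2 -1.56 ± 0.32, edgeR adjusted p = 0.129). Hipk3, Tab2, Marchf7, Med13, Smad4, Klf3, Pde3b and Fnip1 had log2 changes between -1.55 for Med13 and -1.21 for Hipk3, and Nfasc one of -6.29, each with an edgeR adjusted p = 0.173. Vwf, the von Willebrand factor gene that marks platelet-biased HSCs, averaged 123 CPM in aged and 21.1 in young cells without passing, and Selp, the P-selectin gene, 34.9 and 12.

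edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 5 of 15127 genes, all higher in aged. At an unadjusted p under 0.05 there were 2450 genes, 921 higher and 1529 lower, where 756 are expected by chance. In 3738 genes (24.7%) the 3 aged libraries did not overlap the 3 young ones, 1298 higher and 2440 lower, where chance gives 10%. The median log2 change was -0.126 over all genes tested and 0.047 over those above 50 CPM. The young libraries held low counts over many genes silent in the others, and the excess of lower genes was not separated from that. DESeq2 called 1889 genes, 475 higher and 1414 lower, and limma-voom 18, 9 each way. edgeR's newer quasi-likelihood method, added after the data were seen, called 9 higher and 12 lower, which include 2 of the 5. The edgeR count was 80 without young 3, 20 without aged 2, 15 without young 1, 13 without young 2 and 2 without aged 3. In that last fit Ramp2, Gpx8 and Spryd4 lost their calls with edgeR adjusted p of 0.0951, 0.136 and 0.0538. Spryd4 also lost its call without aged+Ri 3 (edgeR adjusted p = 0.0587). With only the 2 groups in the model, Snrpn, Ramp2, Gpx8 and Spryd4 lost their calls (edgeR adjusted p = 0.2, 0.145, 0.119 and 0.2). With young 1 as the only young library, an alternative added after the Y-chromosome transcripts were seen, 358 genes were called.

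**Figure D2:**
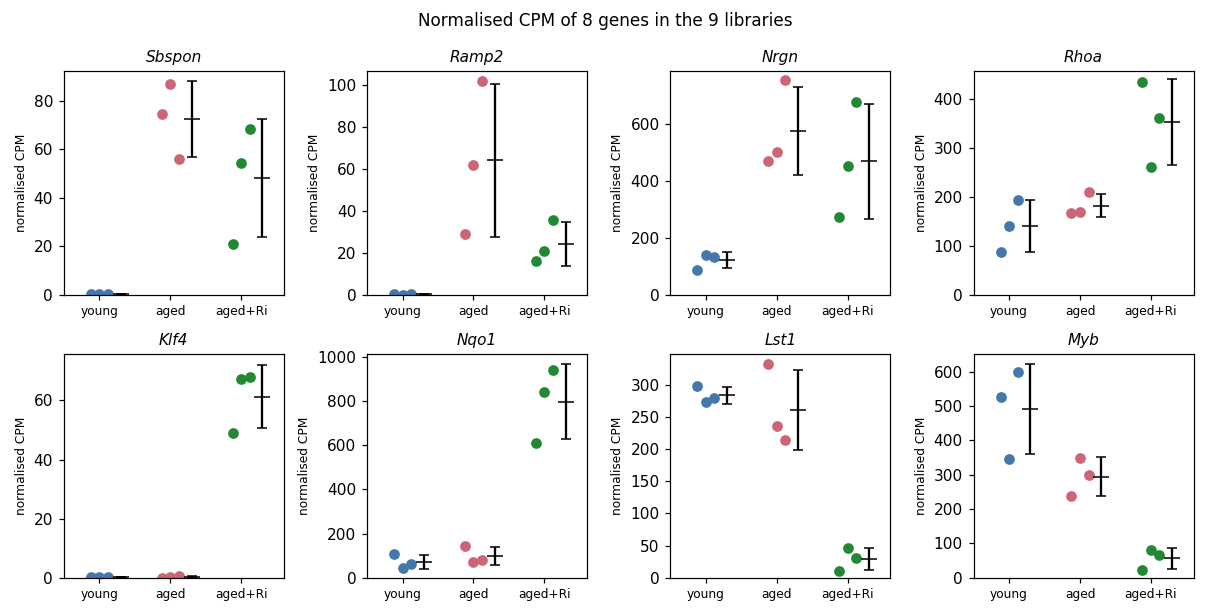
Normalised CPM of 8 genes, 1 point per library, with the group mean and SD (n = 3) beside the points; each panel has its own axis. Sbspon and Ramp2 lie under 1 CPM in the 3 young libraries, and Klf4 lies under 1 CPM in the 6 libraries without the inhibitor.

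Aged cells kept with the RhoA inhibitor were compared with aged cells kept without it, to ask what the inhibitor does to the transcriptome of aged LT-HSCs. Stress-response genes rose as groups, and myeloid, mast cell, lymphoid, and mature T, NK and B cell genes fell as groups, while 0 single genes passed over the whole table. These group calls are from camera at its preset correlation, and each was lost with an estimated one, where the smallest camera adjusted p over the lists was 0.169. The gene with the smallest p was Nqo1, a quinone reductase and classical target of the transcription factor NRF2, at 797 ± 168 CPM with the inhibitor and 99.7 ± 40 without (n = 3 each; log2 3.00 ± 0.40, edgeR adjusted p = 0.0567). Klf4, a zinc-finger transcription factor, was at 61.3 ± 10.8 and 0.2972 ± 0.396 CPM (log2 7.68 ± 1.28, edgeR adjusted p = 0.124). Lst1, a leukocyte transmembrane adaptor gene, was lower, at 29.1 ± 17.8 and 260.4 ± 62.4 CPM (log2 -3.16 ± 0.46, edgeR adjusted p = 0.0567). Rhoa itself, on chromosome 9 at 108306129 to 108337934, was at 352 ± 87.7 CPM with the inhibitor and 181 ± 23.6 without (log2 0.96 ± 0.34, edgeR adjusted p = 0.434).

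Genes of the unfolded protein and integrated stress response rose as a group with a median log2 change of 0.99 (camera adjusted p = 1.76e-14; alternatives from 5.72e-23 to an adjusted p = 0.333 with an estimated correlation). Of its 56 members 49 were positive, and 13 were higher at an edgeR p adjusted over the list alone. Slc3a2, the heavy chain of amino-acid exchangers, was at 952 ± 660 CPM with the inhibitor and 268 ± 49.8 without. Dnajb9, a chaperone of the endoplasmic reticulum, was at 449.9 ± 373 and 117 ± 23.9 (edgeR adjusted p = 0.228 and 0.285 for these 2 genes). Heat shock and protein folding genes rose with a median of 0.55, 36 of 39 members positive and 3 higher over the list alone (camera adjusted p = 1.1e-08; alternatives from 2.09e-09 to an adjusted p = 0.169 with an estimated correlation). Among them, Sqstm1, an autophagy receptor, was at 879 ± 313 and 377 ± 110 CPM (edgeR adjusted p = 0.346). Immediate early and stress genes rose with a median of 0.58 and 4 members higher over the list alone (camera adjusted p = 3.33e-05; alternatives from 4.28e-06 to an adjusted p = 0.169 with an estimated correlation). Besides Klf4, the Krüppel-like factor gene Klf6 was at 352 ± 45.7 and 119 ± 11.6 CPM and the nuclear receptor gene Nr4a1 at 35.7 ± 29.4 and 2.71 ± 1.12 (edgeR adjusted p = 0.127 and 0.228). Without aged+Ri 1 the median of the unfolded protein and integrated stress response was 0.49. In batch 1 and in batch 2 the medians were 1.65 and 0.77 for unfolded protein, 0.71 and 0.54 for heat shock, and 0.40 and 0.63 for immediate early genes.

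NRF2 and xenobiotic response genes rose with a median of 0.57, and 26 of 38 members were positive (camera adjusted p = 2.95e-06; alternatives from 2.93e-08 to an adjusted p = 0.171 with an estimated correlation). Nqo1 was the 1 member higher over the list alone. Slc7a11, the cystine transporter, was at 99.2 ± 83.2 CPM with the inhibitor and 13.1 ± 8.45 without (edgeR adjusted p = 0.346). Fth1, the ferritin heavy chain, was at 17290 ± 3290 and 7142 ± 2710 (edgeR adjusted p = 0.355). Glycolysis and hypoxia genes rose with a median of 0.31 and 28 of 40 members positive (camera adjusted p = 0.0455; alternatives from 0.0249 to an adjusted p = 0.271 with an estimated correlation). Vegfa was at 187 ± 75 and 60.4 ± 22.7 CPM (edgeR adjusted p = 0.285). The glycolysis and hypoxia call was lost without young 1, aged 2 or aged+Ri 2, with camera adjusted p of 0.0532, 0.2 and 0.164, and with the stricter filter or batch (0.0573 and 0.0774). In batch 1 and in batch 2 the medians were 0.21 and 0.97 for NRF2 genes, and 0.12 and 0.40 for glycolysis genes.

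Myeloid genes fell as a group with a median log2 change of -4.01, or -3.84 with the members at 0 to 3 counts set to their bound (camera adjusted p = 5.63e-13; alternatives from 4.43e-19 to an adjusted p = 0.333 with an estimated correlation). Of its 41 members 34 were negative, and at an edgeR p adjusted over the list alone 20 were lower and 1 was higher. Hk3, a myeloid hexokinase gene, had 1 count in the aged+Ri and 1913 in the aged group, a ratio of 1288 (counting interval 230.9 to 50900; edgeR adjusted p = 0.127). Ly6c2, a monocyte surface antigen, was at 4.27 ± 1.96 and 169.7 ± 227 CPM (edgeR adjusted p = 0.151). Mast cell and basophil genes fell with a median of -3.20 over 12 members (camera adjusted p = 4.13e-06; alternatives from 3.46e-08 to an adjusted p = 0.169 with an estimated correlation). Fcer1a, a chain of the IgE receptor, had 1 count in the aged+Ri and 3942 in the aged group, a ratio of 2654 (counting interval 476.1 to 104900; edgeR adjusted p = 0.0907). Lymphoid genes fell with a median of -1.53, 35 of 38 negative (camera adjusted p = 1.06e-08; alternatives from 4.25e-15 to an adjusted p = 0.333 with an estimated correlation). Genes of mature T, NK and B cells, which the lineage depletion of the sort should remove, fell with a median of -2.97, or -2.90 with bounded members, 25 of 26 negative (camera adjusted p = 9.99e-08; alternatives from 5.12e-14 to an adjusted p = 0.333 with an estimated correlation). Nkg7, a granule gene of cytotoxic lymphocytes, was at 9.35 ± 12.5 and 103.5 ± 62.3 CPM (edgeR adjusted p = 0.335). Much of the size of these falls came from aged 3: without it the medians were -1.81 for myeloid, -1.20 for mast cell and basophil, and -1.48 for mature T, NK and B cells, each still past the test (camera adjusted p = 8.98e-11, 0.00279 and 0.00092). The lymphoid median was -3.02 without aged+Ri 3. Within batch 1 the medians were -1.82 for myeloid and 0.11 for mature T, NK and B cell genes, and within batch 2 they were -2.06 and -3.06. Lymphoid genes had medians of -0.67 and -2.03 in these batches, and mast cell and basophil genes -0.48 and -2.09.

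HSC identity and quiescence genes fell with a median of -0.68, and 38 of 43 members were negative (camera adjusted p = 6.54e-07; alternatives from 5.25e-09 to an adjusted p = 0.393 with an estimated correlation). Lmo2, a transcriptional adaptor of HSCs, was at 320 ± 146 CPM with the inhibitor and 732 ± 150 without (edgeR adjusted p = 0.419). Procr, an HSC surface marker, went the other way, at 269 ± 123 and 100.6 ± 38.1 CPM (edgeR adjusted p = 0.367). Megakaryocyte and platelet genes fell with a median of -0.35, and 4 were lower over the list alone (camera adjusted p = 0.00509; alternatives from 7.59e-05 to an adjusted p = 0.388 with an estimated correlation). Gp9, a platelet glycoprotein, was listed at 0 in the 3 aged+Ri libraries and was at least 253-fold lower there, taking 3 counts over the group as the floor (edgeR adjusted p = 0.276). Without aged+Ri 1 the megakaryocyte and platelet call was lost (median -0.33, camera adjusted p = 0.143), and its median was -0.53, -0.68 and -0.56 without aged 3, aged+Ri 2 and aged+Ri 3. With the stricter filter the megakaryocyte and platelet call was lost too (camera adjusted p = 0.113). The HSC identity and quiescence median was -1.13 without aged+Ri 2. Within batch 1 and within batch 2 the medians were -1.48 and -0.40 for HSC identity and -0.99 and -0.35 for megakaryocyte genes.

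All 13 mitochondrially encoded genes were lower with the inhibitor, and the list fell with a median of -0.70 (camera adjusted p = 3.18e-05; alternatives from 1.66e-07 to an adjusted p = 0.496 with an estimated correlation). mt-Co3, a subunit of cytochrome c oxidase, was at 2179 ± 439 and 3573 ± 829 CPM (edgeR adjusted p = 0.458). Their share of all counts was 2.01% ± 0.507 in aged+Ri and 2.94% ± 0.522 in aged libraries. Nuclear genes of oxidative phosphorylation fell with a median of -0.35, 61 of 74 negative (camera adjusted p = 0.000118; alternatives from 4.35e-07 to an adjusted p = 0.662 with an estimated correlation). Ndufb7 was at 210.9 ± 29.6 and 386 ± 92.8 CPM (edgeR adjusted p = 0.434). Genes for ribosomal proteins fell with a median of -0.26, 72 of 81 negative (camera adjusted p = 0.00927; adjusted p = 0.884 with an estimated correlation, alternatives from 1.3e-11 to 0.9). Rplp1 was at 857 ± 41.5 and 1316 ± 492 CPM (edgeR adjusted p = 0.53). The call for ribosomal proteins was lost without aged 1 (median -0.10, camera adjusted p = 0.9), without aged 2 (0.0706) and without aged+Ri 2 (0.135), and the median was -0.52 without aged 3. Within batch 1 and within batch 2 the 3 lists had medians of -0.75 and -0.81, -0.45 and -0.56, and -0.58 and -0.36.

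Other genes named by the fixed rule did not pass either. On the higher side, Tsc22d1, a transcriptional regulator, was at 6363 ± 1660 and 1849 ± 108 CPM (edgeR adjusted p = 0.0567). Prdx6, a peroxiredoxin, was at 1527 ± 76.7 and 568 ± 38 (edgeR adjusted p = 0.14). Ifrd1, Crem, Usp53 and Spata6 had log2 changes of 1.74, 3.08, 2.90 and 1.89, with edgeR adjusted p between 0.127 and 0.213. Ifit3, an interferon-induced gene, had 1 count in the aged and 2568 in the aged+Ri group, a ratio of 3814 (counting interval 683.9 to 150700; edgeR adjusted p = 0.127). Of these, 2263 counts came from aged+Ri 3, and Ifit3 was at 63.9 CPM there and at 3.62 and 3.04 in aged+Ri 1 and 2. On the lower side, Myb, a transcription factor of proliferating progenitors, was at 56.6 ± 30.1 and 295 ± 55.7 CPM (edgeR adjusted p = 0.127). Cdk6, a kinase of the G1 phase, was at 28.5 ± 10.5 and 113 ± 8.64 (edgeR adjusted p = 0.132). Ptpn18, Pcp4l1, M1ap and Myl10 had log2 changes of -1.66, -2.64, -4.06 and -3.55, with edgeR adjusted p between 0.127 and 0.132.

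With edgeR's quasi-likelihood test 0 of 15127 genes passed (smallest adjusted p = 0.0567). At an unadjusted p under 0.05 there were 1382, where 756 are expected, and 2525 (16.7%) had groups that did not overlap, where chance gives 10%. DESeq2 called 427 genes, limma-voom 55, and edgeR's newer quasi-likelihood method 4. With young 1 as the only young library 40 were called. The edgeR count was 6 without aged 1, 5 without young 3, 2 without young 1 or aged+Ri 1, 1 without young 2, aged 2 or aged+Ri 2, and 0 without aged 3 or aged+Ri 3. The labels describe no solvent for the untreated cells, so the comparison does not separate the inhibitor from any solvent.

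**Figure D3:**
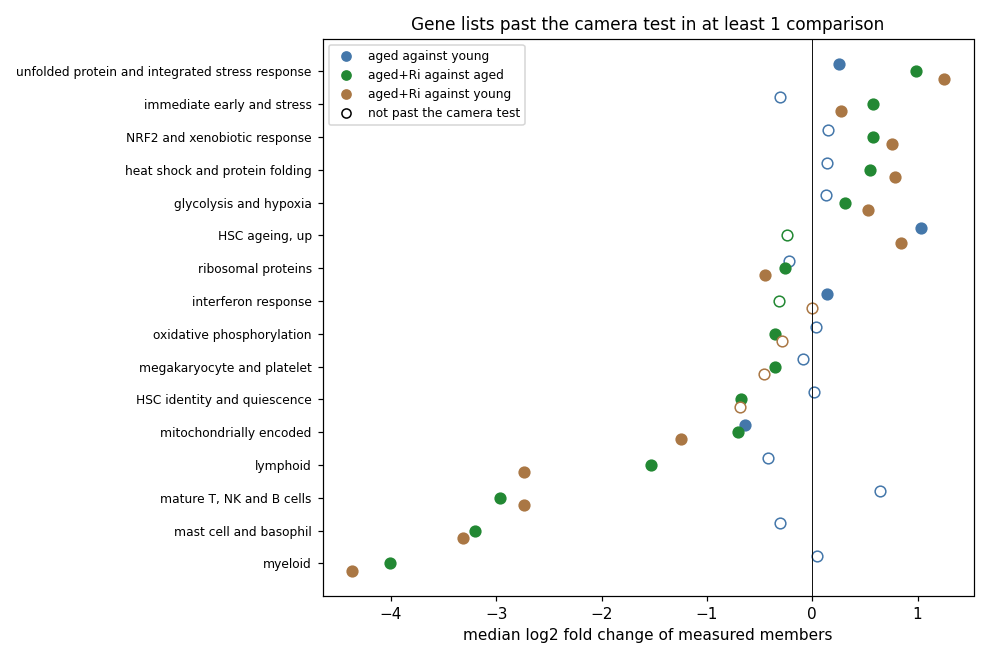
Median log2 fold change over the measured members of each of the 16 gene lists that passed the camera test in at least 1 comparison, 1 point per comparison; filled points passed (adjusted p under 0.05 at a preset correlation of 0.01) and open points did not. The list of genes higher in aged HSCs lies at 1.03 in aged against young and at -0.24, not past the test, in aged+Ri against aged.

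Whether the inhibitor moved ageing-related transcripts back was asked of the list and of single genes. The list of genes higher in aged HSCs had a median log2 change of -0.24 in aged+Ri against aged, with 33 of 64 members negative, and did not pass (camera adjusted p = 0.749; fry adjusted p = 0.832). Its median was -0.09 without aged 1 and -0.42 without aged 3, and it was -0.56 within batch 1 and -0.12 within batch 2. Of the 5 genes called with age, 3 had the opposite sign with the inhibitor (60%, exact Clopper-Pearson 95% interval 14.7 to 94.7). None of the 5 was called in aged+Ri against aged by edgeR's quasi-likelihood test. Sbspon was at 72.5 CPM in aged and 48.0 in aged+Ri cells, and Ramp2 at 64.2 and 24.1, against under 1 CPM in young cells for both. Vwf averaged 123 CPM in aged, 37.7 in aged+Ri and 21.1 in young cells, and Selp 34.9, 43.1 and 12, without passing in any comparison.

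Both changes contain the aged libraries, so opposite signs arise without any effect. Among the 200 genes with the smallest p for age, 68.5% had the opposite sign with the inhibitor. Unchanged groups simulated with the same shared aged libraries gave 88.2% (range over 20 draws 83.5 to 94). The simulated groups held no difference with age, so their top genes rest on the spread of the shared libraries alone. A real difference with age would lower the share without any effect of the inhibitor, so the gap between these shares decides nothing. Over all genes, the covariance of the log2 CPM changes was -0.61, and the simulated value was -0.71 (range -0.74 to -0.67). For the 3601 genes over 50 CPM it was 0.06, and the simulated value was -0.16. With the aged libraries split so that none entered both changes, the covariance was 0.47, -0.11 and -0.01 in the 3 splits, a mean of 0.11. For the genes over 50 CPM it was 0.24, 0.11 and 0.18, a mean of 0.18. These splits still shared sequencing batches, as aged 1 was in batch 1 with aged+Ri 1. Likewise, aged 2 was in batch 2 with aged+Ri 2 and aged+Ri 3. A batch effect could therefore enter both changes. The mean correlation across genes with the young libraries was lower by a difference of -0.0127 in aged+Ri than in aged libraries (two-sided exact permutation p = 0.4).

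Aged cells kept with the inhibitor were last compared with young cells, which joins the difference in age with that in treatment. The lists of stress-response, NRF2 and ageing-related genes rose as groups, and those of mitochondrially encoded, ribosomal, myeloid, lymphoid, mast cell, and mature T, NK and B cell genes fell as groups. Each of these calls from camera at its preset correlation was lost with an estimated one (camera adjusted p between 0.169 and 0.866), and 0 members of the ribosomal and mature T, NK and B cell lists were called by edgeR, also over the list alone. Snrpn had a ratio of group counts of 1042 (counting interval 356.3 to 5057; edgeR adjusted p = 0.00294). Spryd4 rose by 8.44 ± 1.03 on the log2 scale to 20.6 ± 8.81 CPM (edgeR adjusted p = 0.00354), and Sbspon by 8.40 ± 0.70 to 48.0 ± 24.4 CPM (edgeR adjusted p = 0.000233). Klf4 rose from 0.3699 ± 0.0553 to 61.3 ± 10.8 CPM (log2 7.36 ± 1.27, edgeR adjusted p = 0.0188). Ifit3 rose from 0.12 ± 0.0948 to 23.5 ± 35 CPM (log2 7.60 ± 1.64, edgeR adjusted p = 0.0394). Among the genes past the threshold that met the naming rule, the largest falls were those of Rag2, a recombinase of lymphocyte precursors, Ms4a6c, Hk3, C3, the complement component, and Cd33, a myeloid lectin, each with 1 or 2 counts in the aged+Ri group. Their ratios of young over aged+Ri were 3477 for Rag2 (counting interval 623.6 to 137400), 3326 for Ms4a6c (596.5 to 131400) and 1515 for Hk3 (271.5 to 59880), with edgeR adjusted p of 0.0453, 0.0257 and 0.021. They were 1269 for C3 (351 to 10490) and 1186 for Cd33 (327.9 to 9797), with edgeR adjusted p of 0.0281 and 0.0298. The young libraries were uneven for these genes. Rag2 was at 72.97 CPM in young 3 and at 9.706 and 7.601 in young 1 and young 2. C3 was at 56.68 CPM in young 3 and at 0.8897 in young 1, where Hk3 was at 0.4853. In young 2, Ms4a6c and Cd33 were at 0.3571 and 0.4081 CPM.

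The list of genes higher in aged HSCs rose with a median of 0.84, 49 of 64 positive, 10 called higher over all genes, and 17 higher and 2 lower over the list alone (camera adjusted p = 4.08e-12; alternatives from 1.23e-16 to an adjusted p = 0.171 with an estimated correlation). Jam2, a junctional adhesion molecule, was at 373 ± 138 CPM and 58.9 ± 17.1 in young cells, and Cd9, a tetraspanin, at 2620 ± 903 and 747 ± 51.2 (edgeR adjusted p = 0.0116 and 0.016). Genes of the unfolded protein and integrated stress response rose with a median of 1.25, 10 called over all genes and 26 over the list alone (camera adjusted p = 5.63e-13; alternatives from 1.08e-22 to an adjusted p = 0.388 with an estimated correlation). Asns was at 494 ± 324 and 35.1 ± 19.9 CPM and Pdia6, a disulphide isomerase, at 528 ± 465 and 39.4 ± 14.8 (edgeR adjusted p = 0.0131 and 0.0188). Heat shock and protein folding genes rose with a median of 0.78 and 2 called over all genes (camera adjusted p = 6.43e-08; alternatives from 5.97e-12 to an adjusted p = 0.169 with an estimated correlation). Ubb, a polyubiquitin gene, was at 8478 ± 2080 and 2321 ± 676 CPM (edgeR adjusted p = 0.016). NRF2 and xenobiotic response genes rose with a median of 0.75 and 4 called over all genes, Nqo1, Ftl1, Gstp1 and Fth1 (camera adjusted p = 2.47e-06; alternatives from 1.43e-08 to an adjusted p = 0.171 with an estimated correlation). Nqo1 was at 797 ± 168 and 70.6 ± 32.3 CPM (edgeR adjusted p = 0.00304). The median of the list HSC ageing, up was 1.49 without young 1, and that of the unfolded protein and integrated stress response was 0.71 without aged+Ri 1.

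Glycolysis and hypoxia genes rose with a median of 0.53 (camera adjusted p = 0.0203; alternatives from 5.83e-05 to an adjusted p = 0.171 with an estimated correlation). Both called members encode glycolytic enzymes, Eno1 at 222 ± 37.1 against 53.9 ± 11 CPM and Aldoa at 772 ± 46.5 against 302 ± 28.8 (edgeR adjusted p = 0.0222 and 0.0258). Immediate early and stress genes rose with a median of 0.28 (camera adjusted p = 0.0287; alternatives from 9.22e-05 to an adjusted p = 0.333 with an estimated correlation). Klf4 and Klf6 were called higher and Irf2bp2, a transcriptional corepressor, called lower (edgeR adjusted p = 0.0188, 0.0188 and 0.031). Without young 1, glycolysis and hypoxia had a camera adjusted p = 0.0584 and immediate early and stress one of 0.112, and without young 3 the latter had 0.0777. Its median was 0.08 without young 1, 0.45 without young 2 or young 3, and 0.16 without aged+Ri 1. The glycolysis and hypoxia call was also lost with the stricter filter, only the 2 groups or batch (camera adjusted p = 0.0925, 0.0655 and 0.057), and the immediate early and stress call with the stricter filter or batch (0.145 and 0.0926). Within batch 2 (batch 1 also holds aged+Ri 1, and young 1 in part), immediate early and stress genes had a median of the opposite sign, -0.11, and glycolysis and hypoxia genes one of 0.09. There the medians were 1.23 for ageing, 0.64 for unfolded protein, 0.60 for heat shock and 0.73 for NRF2 genes.

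All 13 mitochondrially encoded genes were lower, and the list fell with a median of -1.25 (camera adjusted p = 1.62e-08; alternatives from 7.61e-11 to an adjusted p = 0.333 with an estimated correlation). Of the 13 genes 5 were called over all genes and 12 over the list alone. mt-Nd1, a complex I subunit, was at 653 ± 289 and 2287 ± 492 CPM (edgeR adjusted p = 0.0247). The share of the 13 genes was 2.01% ± 0.507 in aged+Ri and 4.43% ± 0.273 in young libraries. Genes for ribosomal proteins fell with a median of -0.45 (camera adjusted p = 0.000213; alternatives from 1.78e-09 to an adjusted p = 0.866 with an estimated correlation). Rps15a was at 606 ± 5.69 and 1464 ± 187 CPM (edgeR adjusted p = 0.0547). Myeloid genes fell with a median of -4.37, or -4.21 with bounded members, 3 called lower and 1, the protease gene Ctsc, called higher (camera adjusted p = 1.23e-07; alternatives from 4.02e-10 to an adjusted p = 0.388 with an estimated correlation). Lymphoid genes fell with a median of -2.74 (camera adjusted p = 9.99e-06; alternatives from 3.99e-08 to an adjusted p = 0.393 with an estimated correlation). Ikzf1, a lymphoid transcription factor, was at 38.2 ± 10.1 and 134 ± 35.9 CPM (edgeR adjusted p = 0.0418), and the lymphoid median was -1.62 without young 3. Mast cell and basophil genes fell with a median of -3.32, or -3.15 with bounded members (camera adjusted p = 0.00253; alternatives from 0.000346 to an adjusted p = 0.171 with an estimated correlation). Il4 was at 2.47 ± 2.31 and 50.3 ± 4.55 CPM (edgeR adjusted p = 0.0351). Mature T, NK and B cell genes fell with a median of -2.74 (camera adjusted p = 0.028; alternatives from 0.00427 to an adjusted p = 0.662 with an estimated correlation). That call for mature T, NK and B cells was lost without young 1, young 3, aged 2, aged+Ri 1 or aged+Ri 2, with camera adjusted p of 0.125, 0.0615, 0.051, 0.0875 and 0.107, and without a filter, with the stricter one, only the 2 groups or batch (0.208, 0.151, 0.141 and 0.292). The call for ribosomal proteins was lost without a filter (camera adjusted p = 0.248). Within batch 2 the medians were smaller for lymphoid (-0.88), mast cell and basophil (-1.63) and mature T, NK and B cell genes (-0.52), and they were -3.72 for myeloid, -0.80 for mitochondrially encoded and -0.58 for ribosomal protein genes.

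edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 219 genes, 145 higher and 74 lower in aged+Ri than in young cells. At an unadjusted p under 0.05 there were 3546 genes, 1371 higher and 2175 lower. In 4889 genes (32.3%) the groups did not overlap, 1878 higher and 3011 lower, where chance gives 10%. The median log2 change was -0.241 over all genes tested and 0.0865 over those above 50 CPM. Here too the excess of lower genes was not separated from the low counts in the young libraries. DESeq2 called 2943 genes, 830 higher and 2113 lower, and limma-voom 644, 327 higher and 317 lower. All 5 genes called with age were among the 145, and both comparisons use the same young libraries, so this overlap is no separate evidence. The count was 532 without young 3, 132 without aged 3, 121 without aged 2, 113 without aged 1, 109 without young 1, 34 without aged+Ri 1 and 18 without aged+Ri 3, and 735 with young 1 as the only young library. Ifit3 kept its call in the fits without young 3 or aged+Ri 2 and lost it without each of the other 7 libraries, and Rag2 lost its call without 7 of the 9. Without aged+Ri 3 the log2 change of Ifit3 was 4.80 (edgeR adjusted p = 0.179). Ifit3 also lost its call with limma-voom (limma-voom adjusted p = 0.0576), and Rag2 without a filter (edgeR adjusted p = 0.0737). Ms4a6c, Hk3, C3 and Cd33 each lost their calls without any 1 of the 3 aged+Ri libraries (edgeR adjusted p between 0.0509 and 0.119), Cd33 also without young 1 (0.0536), and Klf4 without aged+Ri 3 (0.0879). With the sequencing batch in the model Cd33, Ms4a6c and Ifit3 lost their calls (edgeR adjusted p = 0.0633, 0.0582 and 0.123), and with only the 2 groups Ms4a6c, Hk3, C3, Cd33 and Ifit3 did (edgeR adjusted p between 0.0705 and 0.0802).

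Genes of the pathway that the inhibitor addresses did not pass as groups. RhoA and actomyosin genes had medians of -0.05, -0.08 and -0.04 in aged against young, aged+Ri against aged and aged+Ri against young, and the smallest camera adjusted p was 0.449. Targets of SRF and MRTF, transcription factors that respond to actin, had medians of -0.30, 0.01 and -0.04 (smallest camera adjusted p = 0.282), and YAP and TAZ targets -0.15, 0.11 and -0.24 (0.749). Nuclear envelope and lamina genes had medians of -0.50, 0.09 and -0.26 (smallest camera adjusted p = 0.729), heterochromatin genes -0.20, -0.19 and -0.50 (0.207), and adhesion, homing and polarity genes -0.21, 0.27 and -0.09 (0.674). Rhoc averaged 3.05 CPM in young, 15.3 in aged and 42.1 in aged+Ri cells, and Rhob 14, 15.7 and 26.7. Cdc42 averaged 674, 1062 and 1087 and Lmna, the lamin A gene, 9.11, 1.47 and 7.08, and none of these 4 genes passed the edgeR test in any comparison. Lists of S phase genes (medians -0.39, 0.09 and -0.36), of G2 and M phase genes (-0.16, -0.48 and -0.61) and of cholesterol synthesis (0.16, 0.23 and 0.10) did not pass either, with smallest camera adjusted p of 0.641, 0.131 and 0.0979. The G2 and M phase list passed in aged+Ri against aged without aged 1 (median -0.88, camera adjusted p = 1.01e-05) and without aged+Ri 3 (-0.96, 0.00125), in a range over its alternatives of 1.01e-05 to 0.966. In aged against young its median turned to 0.39 without young 3 and to 0.29 without aged 1 (camera adjusted p = 0.0191, range 0.0191 to 0.997). It passed in aged+Ri against young with the stricter filter (camera adjusted p = 0.0261, range 0.0261 to 0.905), with medians over its alternatives from -0.95 to 0.03. Cholesterol synthesis passed in aged+Ri against young without aged+Ri 1 or aged+Ri 3, without a filter and with batch (camera adjusted p = 0.00609, 0.014, 0.00255 and 0.0121, range 0.00255 to 0.801), and its median was -0.39 without aged+Ri 2. It also passed in aged against young without a filter (camera adjusted p = 0.00754) and in aged+Ri against aged without aged+Ri 1 (0.0435), as did in the latter SRF and MRTF targets without aged 3 (0.033) and nucleic acid sensing without aged 2 (0.0401). Without a filter, RhoA and actomyosin genes passed in aged against young and in aged+Ri against young (camera adjusted p = 0.00421 and 0.0081), with medians of 0.01 and -0.06. The median over all genes was -0.567 and -0.858 in those fits. As camera compares a list with the other genes, these passes do not show a change of the RhoA list itself. The medians were 0.09, -0.04 and 0.19 for NF-kB and inflammation, where the first turned negative under DESeq2 size factors, and 0.08, -0.21 and -0.39 for nucleic acid sensing (smallest camera adjusted p = 0.641 and 0.156).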

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

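Young 1 as the only young library and edgeR's newer quasi-likelihood method were added after the results were seen. Of 1220 values of named genes under the alternatives fixed beforehand, over 72 pairs of gene and comparison, 1055 kept their direction and side of the threshold, 46 fell short of it, 104 passed it and 15 changed sign. In aged against young, the count of 5 genes became 1889 with DESeq2, 18 with limma-voom, 20 without a filter, 1 with only the 2 groups, 358 with young 1 alone and 21 with the newer method (2 of the 5 among them), and leaving out 1 library gave 2 (without aged 3) to 80 (without young 3). In aged+Ri against aged, the count of 0 became 427 with DESeq2, 55 with limma-voom, 11 without a filter, 2 with only the 2 groups, 5 with batch, 40 with young 1 alone and 4 with the newer method, and leaving out 1 library gave 0 (without aged 3 or aged+Ri 3) to 6 (without aged 1). In aged+Ri against young, the count of 219 became 2943 with DESeq2, 644 with limma-voom, 57 with only the 2 groups, 735 with young 1 alone and 425 with the newer method, and leaving out 1 library gave 18 (without aged+Ri 3) to 532 (without young 3). With DESeq2 size factors the 3 counts were 5, 0 and 197, and with the stricter filter 6, 0 and 287. The fit with 2 groups tests fewer libraries. In simulated data DESeq2 made 121, 139 and 148 false calls in the 3 comparisons, fewer than its 1889, 427 and 2943 calls here. Those data were drawn with dispersions fitted by edgeR, so they do not settle how many of the DESeq2 calls here are false. Other causes were not tested.

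With an estimated correlation 0 lists passed in each comparison, and with fry 1, 3 and 6. Without a filter 14 lists passed in aged against young, 14 higher and 0 lower, so the call for mitochondrially encoded genes was lost, and leaving out 1 library gave 5 to 10 there. Lists that passed in aged against young in some of these fits included NRF2 and xenobiotic response, HSC identity and quiescence, heat shock and protein folding, oxidative phosphorylation and ribosomal proteins. Cholesterol synthesis and RhoA and actomyosin genes were also among those that passed without a filter. The median log2 change over all genes was -0.567 in aged against young without a filter. As camera compares a list with the other genes, a pass in that fit does not by itself show that a list rose. The share of called ageing genes with the opposite sign was 100% with only the 2 groups, from 1 gene. With the replicate number as a block the counts of genes were 6, 2 and 226, and the median of the ageing list in aged+Ri against aged was 0.0429 in place of -0.24. Same-numbered libraries correlated between -0.0976 and 0.109 after removal of group means, so the numbers did not pair the samples. A replicate block ended the call for glycolysis and hypoxia in aged+Ri against aged (camera adjusted p = 0.0501, in a range over its alternatives of 0.0249 to 0.271) and added one for ribosomal proteins in aged against young (camera adjusted p = 0.0404, in a range of 4.43e-06 to 0.884).

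The values of named genes that changed sign were those of 5 genes, none of them past the test in that comparison. Rhob in aged against young was -0.17 with batch and -0.20 to 0.57 leaving out 1 library, and Klf4 there -2.28 to 0.28. In aged+Ri against aged, Cdc42 was -0.0149 without a filter and -0.17 to 0.17 leaving out 1 library, and Selp -0.13 with batch and -0.40 to 0.72. In aged+Ri against young, Lmna was 0.17 with limma-voom, 0.23 with the replicate block, 1.36 with batch and -0.75 to 0.54 leaving out 1 library. The cause was not tested. At these totals a group of 3 libraries with 0 counts still allows 3 counts, and edgeR missed most simulated 4-fold changes.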

Other observations

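The tests of depth, of sex, of matched myeloid lists and of granule genes were chosen after the results were seen; those of X-linked reads, of independent dropout and of other splits were set before.

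The alpha-globin genes had higher levels in every aged+Ri than in every aged library. Hba-a1 averaged 649 ± 237 CPM in aged+Ri, 14.9 ± 12.8 in aged and 92.4 ± 143 in young cells (n = 3), and Hba-a2 443 ± 163, 11.7 ± 10.1 and 83.5 ± 128; the pair is near-identical and its counts are uncertain. Both were higher in 3 of 3 aged+Ri than in all aged libraries, without passing over all genes (edgeR adjusted p = 0.434 and 0.415). The share of counts from haemoglobin genes was 0.1075% ± 0.0326 in aged+Ri and 0.003595% ± 0.00307 in aged libraries (two-sided exact permutation p = 0.1, the smallest possible; adjusted p = 0.162, Benjamini-Hochberg). The erythroid list as a whole, which holds these globin genes, had a median log2 change of -0.42, with 12 of 26 members positive (camera adjusted p = 0.868), and Car2, a carbonic anhydrase of red cells, was at 1285 ± 321 and 2270 ± 512 CPM (edgeR adjusted p = 0.434). In aged against young and aged+Ri against young the erythroid medians were -1.96 and -1.71, not past the test (camera adjusted p = 0.131 for both).

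Among p53 and senescence genes, Ddb2, a DNA damage sensor, rose from 0.07445 ± 0.0652 CPM in young to 11.1 ± 2.14 in aged+Ri cells (log2 7.15 ± 1.51, edgeR adjusted p = 0.0384), and was at 3.95 ± 2.91 in aged cells. The p53 list did not pass in any comparison (medians -0.26, 0.22 and 0.02, the last negative under DESeq2 size factors; smallest camera adjusted p = 0.0654), but in aged+Ri against young it passed without any 1 of young 2, aged 1, aged 2, aged 3, aged+Ri 1 and aged+Ri 3 (camera adjusted p between 0.00483 and 0.0208), with medians between -0.04 and 0.05, and in aged+Ri against aged without aged+Ri 1 (0.0323). Cdkn2b, an inhibitor of cyclin-dependent kinases, had 2 counts in the aged and 332 in the aged+Ri group, a ratio of 246.5 (counting interval 67.7 to 2044; edgeR adjusted p = 0.335). Macrophage and dendritic cell genes had medians of -0.24, -0.66 and -0.76 (smallest camera adjusted p = 0.58), and stromal and endothelial genes -2.20, 0.32 and -2.01 (0.0807). In aged against young, stromal and endothelial genes passed without young 2, aged 3 or aged+Ri 2 (camera adjusted p = 0.0302, 0.0163 and 0.0309), and erythroid genes with young 1 as the only young library (0.0137).

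The young libraries held low counts over many genes that are silent in the other libraries, and genomic DNA in them is a candidate source. With all libraries thinned to 34358101 counts, the lowest young library still detected 20129 genes and the highest other one 17175, which argues against a difference in depth. DNA would give X-linked silent genes 0.5 as many reads, relative to autosomal ones, in young 2 and 3, which carry Y transcripts, as in young 1; the ratio was 0.705 (bootstrap 95% interval 0.548 to 0.953). Young 3 alone had 0.419 and young 2 0.803, against 0.867 in young 1, so the test left DNA open, as it did a difference between young and aged cells in low-level transcription, which was not tested.

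Some genes lay near 0 in all 3 young libraries and were present with the inhibitor, among them the 5 genes called with age. The test of dropout took genes with at least 5 CPM in every aged+Ri library, which leaves out Gpx8, at 2.611 CPM in aged+Ri 1. Independent dropout in each young library would give 3.13 of 8042 genes under 1 CPM in all 3, where 40 were found (exact Poisson interval 28.6 to 54.5), which argues against independent dropout for most of them. The aged libraries had an excess too, 5 genes against 0.022, so it is not particular to the young ones, and dropout that hits the same genes in every library was not tested. The Y transcripts in young 2 and 3 raise the sex of the mice as another candidate cause. The 5 genes called in aged against young were under 1 CPM in young 1 as well. There Ddx3y and Eif2s3y had 0 counts and Kdm5d and Uty 2 each, so for these genes the low level was not confined to libraries with Y transcripts. The call favoured genes low in all 3 young libraries, so this outcome was largely set by the choice of genes and does not test sex for others. Sex for other genes, age, genetic background of the mouse colonies and a shared handling of the young cells stay open and untested.

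Myeloid genes were lower in aged+Ri than in aged libraries, and the 10 granule genes among them stood highest in aged 3 of all aged libraries: Elane, a neutrophil elastase named here after its values were seen, was at 4236 CPM there, at 108 and 112.5 in aged 1 and 2, and at 6.77 or less in each aged+Ri library. A first test of lower depth or complexity, on the share under 1 CPM in all 3 aged+Ri libraries, gave 23.3% of 30 genes chosen by their aged mean, which lets in genes carried by aged 3, and 5.26%, 1 of 19 genes, with at least 5 CPM in every aged library. A later test took the change from the lowest aged library to the aged+Ri mean. The median of the 19 genes was -2.02, with 13 of them negative. Of 10000 lists matched on level, 0 went as low (mean 0.41, lowest -0.22), which argues against lower depth or complexity that acts on genes independently. The lists were drawn gene by gene, so a loss that takes genes expressed together was not modelled. Fewer granulocytic cells in the aged+Ri libraries may also account for the pattern. Whether such cells differed at the sort, which removes lineage-positive cells, or in the 16 h of culture was not tested. More granulocytic cells in aged 3 may add to the size of the pattern. The change of -2.02 was taken from the lowest aged library, which argues against aged 3 as the whole account for these 19 genes. A loss of such cells would lower 10 granule genes by 1 ratio only if they carried them in fixed proportions and the remaining cells carried none. Cochran's Q (a chi-square over genes, which are not independent) gave 0.0095 as its p against 1 ratio and 0.452 without Prtn3. Prtn3 had the smallest standard error of the 10, 0.755, and stayed at 29.2, 39.54 and 38.15 CPM in the aged+Ri libraries. Unequal ratios can also arise from a loss of mixed cells, so the test cannot separate the accounts. A loss of cells and an effect of the inhibitor on these genes in the stem cells both stay open.

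The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. In aged against young 1 of the 10 splits gave as many genes as the real one, with 5 in the real and at most 2 in another split. DESeq2 gave 1892 there in the real split, fitted with the group labels exchanged, and up to 199 in another. In aged+Ri against aged, 10 of 10 gave 0, the real value, with edgeR; DESeq2 gave 427 in the real and up to 272 in another split, and edgeR had 1382 genes at an unadjusted p under 0.05 in the real split. In aged+Ri against young 1 of 10 gave as many with edgeR, with 219 in the real split and 0 in every other. DESeq2 gave 2947 there in the real split, again with exchanged labels, and up to 143 in another.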
